A study of Oncorhynchus mykiss with 6 samples.

How the data were processed

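Small RNA libraries of rainbow trout head kidney were compared between 3 control samples and 3 samples challenged with IHNV, the infectious hematopoietic necrosis virus of salmonid fish. Groups were taken from the treatment label and replicate numbers from the sample titles. The titles carry the number 48, and the series' design text lists 48 hours among its sampling times, so all 6 samples were read as 1 time point. Total RNA was extracted with Trizol from flash-frozen tissue, per the labels' protocols, and the libraries followed Illumina's standard small RNA procedure. The aligner, miRNA database, miRNA predictor, genome build and any filter are not given in the sources used here. No genome was used here, so no coordinates are reported.

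The authors deposited 1 table of 2549 entries with a whole-number count and a TPM value for each sample, per the file headers. Of these entries, 718 carry a family name (442 families) and 1831 carry the name of a predicted miRNA. Each entry has 1 sequence of 18 to 29 nt. Family names end in -x, -y or -z, and the meaning of these endings is not given in the sources used here. Family names carry no letter for gene copies, so the copies of a duplicated miRNA gene cannot be told apart. A total of 866 entries share 353 sequences with another entry, and a read of such a sequence may have been counted for each of them. In this text a predicted miRNA is identified by its sequence. The deposited TPM values equal the count divided by 1 constant per library, with 0.01 written for a count of 0, as found from the values. They sum to 0.552 to 0.777% above their nominal total, and to 0.0588 to 0.170% above it when each sequence is added once.

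Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, the default expression filter (minimum count of 10, minimum total of 15), robust dispersion and Benjamini-Hochberg adjustment over the 1018 entries that passed the filter. A miRNA was called changed at an adjusted p under 0.05, and every adjusted p of a miRNA given here comes from that test unless another is named. Standard errors are the log2 fold change divided by the square root of the test's F statistic. Levels are TMM-normalized CPM (counts scaled to a fixed library total), as mean ± SD over 3 samples. The 20 miRNA lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation and with fry. The preset value treats members as nearly independent, although entries of the same family or gene cluster can vary together. A list needed at least 3 tested members, which 17 lists had. The groups, the test, the lists, the rule for named miRNAs and the first set of alternatives were fixed before the data were examined.

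The rule for named miRNAs took, in each direction, up to 12 called miRNAs with the largest log2 fold change. These had to average at least 10 CPM, with all IHNV samples on one side of all control samples. It added every tested member of the fish interferon-inducible list and the 5 most abundant miRNAs. From each other list it took up to 4 called members, or the most abundant member where none was called.

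Alternatives were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and total-count scaling, no filter, a minimum mean of 10 CPM, the replicate number as a block, each sample left out in turn, removal of the most abundant miRNA, other thresholds, and limma on log2(TPM + 1) with pseudocounts of 0.1 and 10 beside it. The limma alternatives on TPM used entries of at least 1 TPM in at least 3 samples. Alternatives added after the data were seen removed rodent- and arthropod-lineage families, kept 1 entry per sequence, summed the endings of a family, used family-named entries alone, or used IHNV sample 1 as the only challenged library. A sum over entries of the same family and ending merged nothing, because each name occurs once.

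Library totals ran from 7335472 to 13705959 counts. Intervals of shares are exact 95% Clopper-Pearson intervals, and they and the limit that a count of 0 allows (3 counts) cover counting error only. Replicates were compared before averaging. The chi-square per degree of freedom between replicates of a group lay between 60.1 and 423, so no pair agreed within counting noise. Log CPM of IHNV sample 1 correlated at 0.957 to 0.967 (Pearson) with the controls. It correlated at 0.925 and 0.954 with IHNV samples 2 and 3. The steps were tested on simulated counts of 1018 entries with 3 samples per group. Of 100 entries changed 2-fold, 10% were called. Of 100 changed 4-fold, 68% were called. The changed entries were picked at random, and counts were drawn with the dispersion trend rather than each entry's own dispersion. These shares are therefore not the sensitivity for abundant miRNAs. Among 818 unchanged entries 5 were called, no call had the wrong direction, and the 1 shifted list was called with 0 others. That list was shifted 4-fold and all entries were drawn independently. The simulation therefore does not test list calls among miRNAs that vary together. Figures were drawn with matplotlib 3.10.9.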

Results

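Small RNA was counted in the head kidney, the main blood-forming and a central immune organ of teleost fish, in 3 control rainbow trout samples and 3 samples challenged with IHNV, a rhabdovirus that damages this organ. All 6 sample titles carry the number 48, read as 48 hours after challenge. Control samples 1, 2 and 3 held 10580331, 13705959 and 9967717 counts. IHNV samples 1, 2 and 3 held 7335472, 12374992 and 10460284 counts. The 5 most abundant miRNAs took 47.9 to 55.0% of each library, and the predicted miRNAs took 0.697 to 1.17%. The labels do not say that the samples of a group came from separate fish, so p-values measure only the spread between these samples, which may be technical.

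The comparison of challenged with control samples addresses which miRNAs of the head kidney change during the infection. The largest rise among the miRNAs chosen by the naming rule was that of miR-155-x, a miRNA induced in activated immune cells, which rose 13.4-fold, from 149 ± 34.9 CPM in controls to 1991 ± 405 CPM in IHNV samples (SD, n = 3 each). miR-21-y rose 10.7-fold, from 3067 ± 224 to 32708 ± 5314 CPM. miR-183-x, miR-96-x and miR-182-x, which vertebrates encode in a single gene cluster, rose 7.41-fold, 7.85-fold and 5.25-fold. miR-462 and miR-731, known as interferon-inducible in fish, rose between 2.18-fold and 2.62-fold in the 5 entries that passed the test. miR-2188-y fell 3.22-fold, from 1257 ± 447 to 391 ± 76.5 CPM. Control sample 1 (1771 CPM) lay above control samples 2 and 3 (966 and 1033 CPM).

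With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 47 of 1018 entries changed, 35 upward and 12 downward. Of the 383 tested entries with a family name, 19 rose and 7 fell, and of the 635 predicted entries 16 rose and 5 fell. The 47 entries held 40 distinct sequences, 30 higher and 10 lower. Before adjustment, 195 entries had a p under 0.05. In 260 entries (25.5%) the IHNV samples all lay on one side of the control samples, where chance gives 10% for an entry taken alone. Entries can vary together within a library, and this share was not computed for other splits, so the excess was not tested. Total-count scaling turned the balance, to 32 higher and 71 lower (31.1% higher against 74.5% with TMM), while 42 of the calls were shared. That scaling moved the median log2 fold change of all entries by −0.36, and upper-quartile scaling moved it by −0.12. The count was 29, 27 and 23 without control sample 1, 2 or 3, and 95 and 28 without IHNV sample 1 or 3; of the 95, 35 belonged to arthropod-lineage families.

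**Figure D1:**
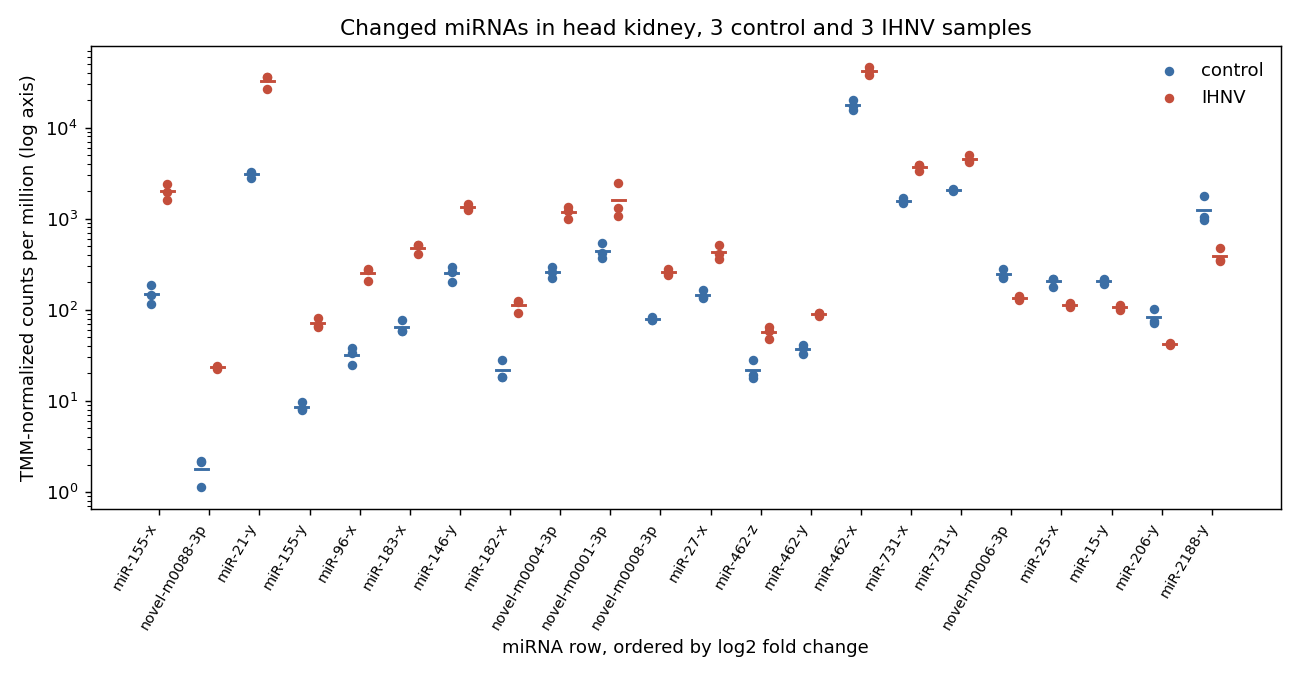
TMM-normalized CPM on a log axis of the changed miRNAs chosen by the size of their change and of the changed miR-462 and miR-731 entries, ordered by log2 fold change. Points are the 3 control (blue) and 3 IHNV (red) samples and bars are group means. The miRNAs chosen by size had to have no overlap between the points of the 2 groups, so their separation is no result. The miR-462 and miR-731 entries were not chosen for this, and their points do not overlap either. miR-21-y lay at 2817 to 3249 CPM in controls and 26583 to 36094 CPM in IHNV samples.

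All 6 tested entries of the fish interferon-inducible list had positive fold changes and 5 rose, or 6 when adjusted over the list alone. miR-462 and miR-731 are encoded side by side in teleosts. miR-462-x (TAACGGAACCCATAATGCAGCTG) was the most abundant of them and went from 17574 ± 2270 to 41667 ± 4351 CPM (log2 fold change 1.25, SE 0.12, adjusted p = 0.00187). miR-731-y (CACCGGGAATTTCGTGTCAGCA) went from 2063 ± 63.2 to 4494 ± 413 CPM (log2 fold change 1.12, SE 0.10, adjusted p = 0.000945), and miR-731-x from 1580 ± 110 to 3685 ± 340 CPM (adjusted p = 0.00100). miR-462-y (log2 fold change 1.27, adjusted p = 0.00348) and miR-462-z (1.39, adjusted p = 0.0255) also rose. The 24-nt sequence of miR-462-z holds all 23 nt of miR-462-x, so reads of these entries may not be separable. miR-731-z, at 1.5 ± 0.503 and 2.87 ± 0.576 CPM, had an adjusted p of 0.21 (log2 fold change 0.92). Likewise, miR-731-z shares 22 nt with miR-731-x. The list stood above the other miRNAs (camera, adjusted p = 2.26e-06), with adjusted p = 0.21 with an estimated correlation. The 6 entries belong to 2 neighbouring miRNAs, so the preset correlation can make the first value too small. The call of miR-462-z was lost without control sample 1 (adjusted p = 0.101), control sample 2 (0.125) or IHNV sample 3 (0.0885).

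Of the 13 tested entries of the inflammation-induced list, 7 rose and none fell, both over all miRNAs and when adjusted over the list alone; 6 did not pass the test. miR-155-x (TTAATGCTAATCGTGATAGGGGT; log2 fold change 3.74, SE 0.24, adjusted p = 0.000401) was accompanied by miR-155-y, which went from 8.60 ± 1.05 to 71.3 ± 9.40 CPM. miR-21-y (CGACAACAGTCTGTAGGCTGT) had the smallest adjusted p of all miRNAs tested (0.000116; log2 fold change 3.41, SE 0.15). miR-21-x, the most abundant miRNA of the table, went from 129808 ± 15874 to 201071 ± 24735 CPM (log2 fold change 0.63, SE 0.13, adjusted p = 0.0438). miR-146, known to be induced by NF-κB and to dampen Toll-like receptor signalling, rose as miR-146-y (254 ± 46.9 to 1338 ± 100 CPM, adjusted p = 0.00047) and as the abundant miR-146-x (51233 ± 8447 to 132284 ± 18654 CPM, adjusted p = 0.00348). The list stood above the other miRNAs (camera, adjusted p = 0.00015), with adjusted p = 0.522 with an estimated correlation. The call of miR-21-x was lost without any 1 of control samples 1, 2 and 3 or IHNV samples 1 and 3 (adjusted p = 0.126, 0.172, 0.134, 0.0759 and 0.142).

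Outside these lists, miR-183-x (TATGGCACTGGTAGAATTCACTG) went from 64.4 ± 10.9 to 477 ± 56.8 CPM (log2 fold change 2.89, SE 0.18, adjusted p = 0.000401). miR-96-x went from 32.3 ± 7.05 to 253 ± 38.5 CPM and miR-182-x from 21.6 ± 5.56 to 113 ± 17.6 CPM (adjusted p = 0.000501 and 0.00183). Predicted entries were among the miRNAs with the largest changes. CACTAGGCTGCATTCAAAACA went from 1.81 ± 0.598 to 23.4 ± 0.905 CPM (log2 fold change 3.68, SE 0.30, adjusted p = 0.000764). CACCGGGAATTTCGTGTCAGCAA, which is the whole miR-731-y sequence with 1 more nucleotide, went from 259 ± 34.3 to 1187 ± 168 CPM (adjusted p = 0.0005). CCTGGATGTGGGTTCCGTCTCC, which is miR-462-y with 2 more nucleotides, went from 78.6 ± 3.57 to 260.1 ± 20.1 CPM (adjusted p = 0.000499). Reads of these 2 entries may not be separable from those of miR-731-y and miR-462-y. TACGGTATGTTATGTAGACTAC went from 444 ± 91.0 to 1608 ± 722 CPM (adjusted p = 0.0455), and its call was lost without control sample 1, 2 or 3 (adjusted p = 0.119, 0.165 and 0.167).

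Among the miRNAs that fell, miR-2188-y (GCTGTGTGAGGTCGGACCTATC) had the largest change of those that averaged at least 10 CPM (log2 fold change −1.69, SE 0.28, adjusted p = 0.0255). miR-15-y fell from 207 ± 14.1 to 105.997 ± 5.70 CPM (log2 fold change −0.97, SE 0.12, adjusted p = 0.00504). Its call was lost under 2 of 23 alternatives, among them the replicate block (edgeR, adjusted p = 0.0722). miR-25-x fell from 205.3 ± 23.2 to 114 ± 6.54 CPM (adjusted p = 0.0177), and the predicted CCAGTATGGCTTGTGCTGCTAAC, which shares 20 nt with miR-457-y, from 244 ± 29.8 to 136 ± 7.01 CPM (adjusted p = 0.0177). The call of miR-2188-y was lost without control sample 3 or IHNV sample 3 (adjusted p = 0.0727 and 0.108). That of miR-25-x was lost without control sample 2, control sample 3 or IHNV sample 3 (0.124, 0.125 and 0.0885), and that of the predicted miRNA without the same samples (0.098, 0.0727 and 0.0885). Over all 23 alternatives, miR-2188-y, miR-25-x and the predicted miRNA lost their calls under 5, 7 and 6. The replicate block was among them for each (edgeR, adjusted p = 0.140).

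The lists of broadly expressed and leukocyte miRNAs had 0 or 1 call each over all miRNAs. In the leukocyte list (miR-142, miR-150, miR-181 and miR-223), 1 of 11 entries fell and none rose, also when adjusted over the list alone, and 6 had an unadjusted p under 0.05. The one that fell was the rare miR-150-y, from 8.75 ± 1.94 to 3.18 ± 0.993 CPM (adjusted p = 0.0492). Its call was lost without control sample 1, 2 or 3 or IHNV sample 2 or 3 (adjusted p = 0.105, 0.197, 0.167, 0.0831 and 0.146). miR-181-x was at 89784 ± 6335 and 107974 ± 8167 CPM (adjusted p = 0.179). In the miR-29 list 1 of 3 entries rose, miR-29-x from 304 ± 50.6 to 882 ± 73.3 CPM (log2 fold change 1.54, adjusted p = 0.00183). The miR-29 list was called higher by camera (adjusted p = 0.0433; adjusted p = 0.522 with an estimated correlation). Leaving out any sample except control sample 3 ended that call (0.101, 0.118, 0.0992, 0.0557 and 0.0635 without control samples 1 and 2 and IHNV samples 1, 2 and 3), as did upper-quartile (0.0937) and total-count scaling (0.0537). In the miR-23/24/27 list 1 of 9 entries rose, miR-27-x from 146.8 ± 15.8 to 430.04 ± 77.8 CPM (log2 fold change 1.55, adjusted p = 0.00289).

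Of the 21 entries of miR-17-92 and its paralogous clusters, none rose and miR-25-x fell; adjusted over the list alone, 2 were higher and 1 lower. Unadjusted, 10 of the 21 had a p under 0.05. The list's adjusted p was 0.13 by camera, and 0.0316 without IHNV sample 2. In the miR-15/16 list 1 of 7 entries fell (camera, adjusted p = 0.198). No entry was called among the 3 of let-7, the 9 of miR-99, miR-100 and their relatives, the 3 of miR-30 and the 4 of the miR-10 Hox-cluster list (camera, adjusted p = 0.963, 0.870, 0.730 and 0.870). The abundant members let-7-x, miR-100-x, miR-30-x and miR-10-x had log2 fold changes of 0.16, 0.30, 0.08 and 0.24. Adjusted over the list alone, miR-23/24/27 and miR-29 kept 1 higher entry each and miR-15/16 1 lower entry. The lists of let-7, of miR-99, miR-100 and their relatives, of miR-30 and of the miR-10 Hox cluster had none. Median and mean had opposite signs in the leukocyte list (0.13 and −0.02), the let-7 list (0.08 and −0.00) and the miR-30 list (0.00 and −0.19); camera followed the sign of the median in the first pair and of the mean in miR-30. The median log2 fold change of 7 of the 17 tested lists, none of them called, took the other sign with total-count scaling.

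**Figure D2:**
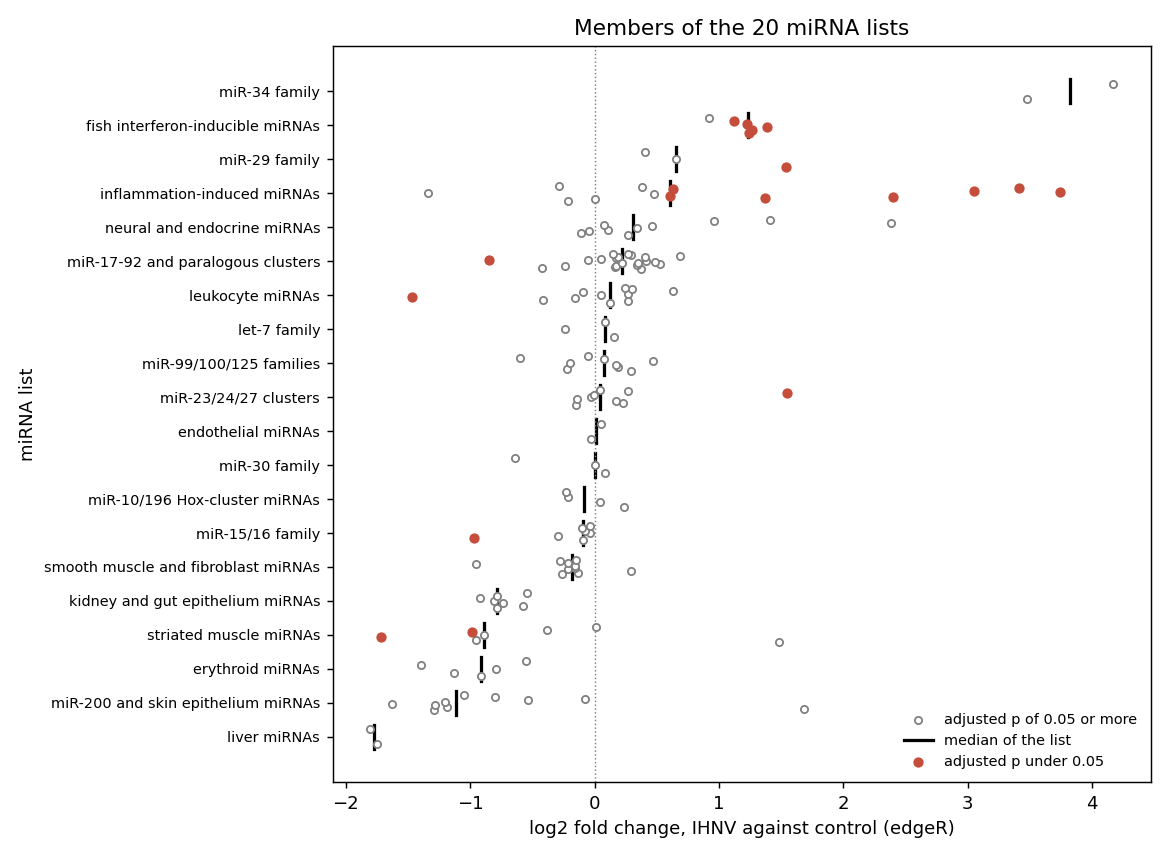
Log2 fold change, IHNV against control, of each tested entry in the 20 miRNA lists, ordered by the list median (black bar). Filled points have an adjusted p under 0.05 in edgeR and open points do not; 5 of 6 interferon-inducible and 7 of 13 inflammation-induced entries are filled and lie above 0, and 6 other lists hold 1 or 2 filled entries each.

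Lists of miRNAs of other cell types that a head kidney dissection could hold were called lower by camera for striated muscle (adjusted p = 0.0205), kidney and gut epithelium (0.0433), miR-200 and skin epithelium (0.0433) and erythroid cells (0.0454). With an estimated correlation their adjusted p was 0.522, 0.612, 0.612 and 0.612, and none of the 7 list calls held with an estimated correlation. In the striated muscle list 2 of 7 entries fell, or 4 when adjusted over the list alone. miR-206-y fell from 82.8 ± 16.5 to 41.8 ± 1.05 CPM (log2 fold change −0.99, adjusted p = 0.0299) and miR-133-x from 4.29 ± 0.985 to 1.28 ± 0.362 CPM (adjusted p = 0.0308). The call of miR-206-y was lost without control sample 2 or 3 or IHNV sample 2 or 3 (adjusted p = 0.109, 0.0991, 0.0581 and 0.108), and that of miR-133-x without any sample except IHNV sample 1 (0.092, 0.098, 0.134, 0.0719 and 0.0683). The muscle list lost its call without IHNV sample 1 (0.0992) or IHNV sample 3 (0.0542), and with upper-quartile (0.0525) or total-count scaling (0.0537).

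No single entry of the erythroid, kidney and gut or miR-200 lists passed the test over all miRNAs; adjusted over the list alone, 1 of 5 erythroid entries was lower and none of the 7 and 10 others. Control sample 1 stood apart in these lists. The log2 ratio of control sample 1 to the mean of control samples 2 and 3 had a median of 1.41 over the erythroid entries, 1.29 over the kidney and gut entries, 1.29 over the miR-200 entries and 3.13 over the 2 liver entries, against −0.13 over the leukocyte entries. miR-451-x, an erythroid miRNA, was at 27546 CPM in control sample 1, at 7829 and 12840 CPM in the other two, and at 9298 ± 276 CPM in IHNV samples (adjusted p = 0.401). The liver miRNA miR-122-x was at 3612 CPM in control sample 1 and at 512 and 292 CPM in the others; its log2 fold change was −1.75, and 0.12 without control sample 1. miR-192-x (−0.78) and miR-200-y (−1.18) had log2 fold changes of −0.17 and −0.38 without it. Without control sample 1 the adjusted p of the erythroid, kidney and gut, and miR-200 lists was 0.298, 0.31 and 0.196. The calls of all 3 lists were also lost without IHNV sample 1 (0.0992 each). Those of the erythroid and the kidney and gut lists were lost without IHNV sample 2 (0.0818 and 0.0989) or 3 (0.0874 and 0.0542), and total-count scaling ended all 3 (0.193, 0.175 and 0.175).

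The smooth muscle and fibroblast list (10 entries; miR-143-y at 26949 ± 479 and 24580 ± 3062 CPM) and the neural and endocrine list (10 entries; miR-7-x at 745 ± 61.6 and 945 ± 153 CPM) had no call over all miRNAs or adjusted over the list alone (camera, adjusted p = 0.163 and 0.209). The endothelial, miR-34 and liver lists held 2 tested entries each, too few for a list test, with no call in either adjustment. The 12 lists without a call over all miRNAs held 67 tested entries, of which 7 had an unadjusted p under 0.05 in edgeR and 0 were called by DESeq2 or limma-voom. miR-126-y, an endothelial miRNA, was at 89217 ± 12053 and 92491 ± 12965 CPM. miR-26-x, another of the 5 most abundant miRNAs, had a log2 fold change of −0.20 (adjusted p = 0.254), and of −0.56 with total-count scaling (adjusted p = 0.0090).

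Families described in rodents or arthropods rather than in fish were also counted, and they were unevenly spread. Of the counts of IHNV sample 2, 0.388% (95% interval 0.384 to 0.391%) belonged to rodent-lineage families, against 0.0130% (0.0123 to 0.0137%) in control sample 1 and 0.00451% (0.00404 to 0.00503%) in IHNV sample 1, the highest and lowest of the other libraries. Arthropod-lineage families took 1.21% (1.21 to 1.22%) of IHNV sample 2 and 1.43% (1.43 to 1.44%) of IHNV sample 3, against 0.204% (0.202 to 0.207%) in control sample 1 and 0.0752% (0.0732 to 0.0772%) in IHNV sample 1. None of the 13 rodent-lineage and 27 arthropod-lineage entries tested was called changed by edgeR, where 0 and 19 had an unadjusted p under 0.05. limma-voom called none and DESeq2 called 21 arthropod-lineage entries. With these families removed 57 entries changed, 46 of them shared with the 47. With IHNV sample 1 as the only challenged library, assumed to vary like the controls, 32 entries changed, 28 of them shared. Some families of the lists moved with these libraries. miR-34-x had 23387 counts in IHNV sample 2 and 258 to 896 in the other libraries, and its log2 fold change of 3.48 (adjusted p = 0.304) was −0.09 without IHNV sample 2. miR-9-x of the neural list had 461 and 463 counts in IHNV samples 2 and 3, 11 in IHNV sample 1 and 68 to 83 in controls. miR-200-x had 1579 and 1594 counts in IHNV samples 2 and 3 and 101 in IHNV sample 1, and miR-1-y of the muscle list had 1431 and 1963 counts in IHNV samples 2 and 3 and 498 to 621 in controls.

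**Figure D3:**
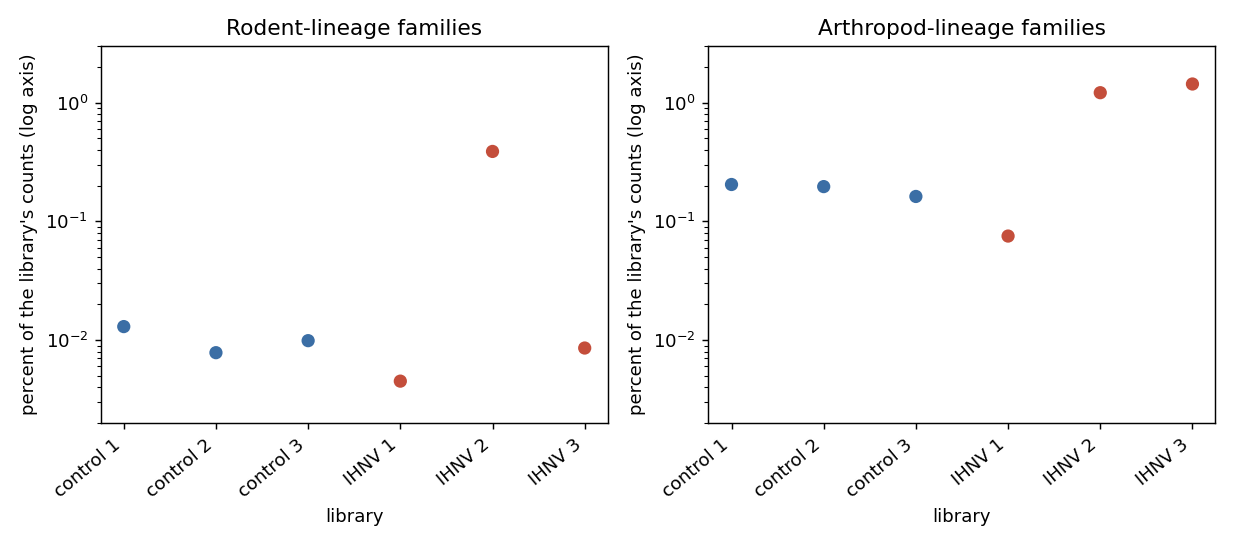
Percent of each library's counts that belong to rodent-lineage (left) and arthropod-lineage (right) miRNA families, on a log axis, for the 3 control (blue) and 3 IHNV (red) samples. IHNV sample 2 lies at 0.388% for rodent-lineage families and IHNV samples 2 and 3 at 1.21 and 1.43% for arthropod-lineage families, above all other libraries.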

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

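The alternatives that removed families of other animals, kept 1 entry per sequence, summed the endings of a family, used family-named entries alone, or kept IHNV sample 1 as the only challenged library were chosen after the data were seen. Against 47 changed miRNAs, DESeq2 called 77 (57 higher, 20 lower; 42 shared; 21 of arthropod-lineage families), total-count scaling 103, and limma on TPM 99, 94 and 90 with pseudocounts of 1, 0.1 and 10 (27 higher in each). Summed endings gave 30, family-named entries alone 19, and an unadjusted p under 0.05 with a 2-fold change 118; leaving out 1 sample gave 23 to 95. Apart from the replicate block, the other alternatives gave 32 to 57. Against 7 called lists, total-count scaling gave 2, an estimated correlation 0, and leaving out 1 sample 2 to 7. fry called 6 lists, 4 of them among the 7: it lost the erythroid, kidney and gut, and miR-200 lists (adjusted p = 0.309, 0.317 and 0.317) and added miR-23/24/27 and miR-15/16 (0.0126 and 0.0411). Of the 27 named miRNAs called changed, 15 were called under every alternative run for them (23 each, against 26 for the count). The call was lost under at least 1 alternative for 12, and none changed sign. Of the 15 not called, 9 changed sign under at least 1 alternative. With total counts and with limma on TPM at all 3 pseudocounts, miR-30-x (0.08) was called at −0.28 and miR-26-x (−0.20) at −0.56. The total-count alternative changed the scaling alone; those on TPM also changed the test and the filter, and the summed table also merged counts, and these parts were not separated. The cause of the other shifts was not tested.

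With the replicate number as a replicate block the count was 18, all higher, and all 18 were among the 47. Deviations of same-numbered samples correlated at −0.13, −0.13 and 0.036, and those of differently numbered samples at −0.077 to 0.173. These values gave no sign that the numbers pair the samples. They cannot exclude a batch shared by same-numbered samples. The block ended the call of the erythroid list (adjusted p = 0.0568) and of 12 named miRNAs, and changed no other call of a list or named miRNA.

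In the 10 splits of the 6 samples into groups of 3, 1 split, the real one, gave as many as 47 miRNAs, and the highest of the others gave 0. For lists 1 split, the real one, gave 7, and the highest other gave 4. With 10 splits no share under 0.05 can be reached. Depth limits the rare miRNAs: the limit that 3 counts set lies between 0.194 and 0.458 TMM-normalized CPM.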

Other observations

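The comparison of -x with -y entries, the lists of other animals' families, and the tests of rodent or arthropod RNA, of a response of these families, of other animals' RNA behind the changed ratios, of tissue RNA in control sample 1 and of the rarer entry rising were chosen only after the result was seen. Within several families, the -x and -y entries changed by different amounts. Of 89 families with both entries tested, the log2 ratio of -x to -y changed in 19 (limma on log2 of counts + 0.5, Benjamini-Hochberg adjusted), and 32 had an unadjusted p under 0.05. In miR-21 the ratio went from 5.40 ± 0.25 in controls to 2.63 ± 0.38 in IHNV samples (SD, n = 3; difference −2.77, SE 0.23, adjusted p = 0.00196 by limma). In miR-146 it changed by −1.04 (SE 0.11), in miR-27 by 1.27 (SE 0.19), in miR-15 by 0.87 (SE 0.10) and in miR-25 by −0.89 (SE 0.11). In miR-15 and miR-25 the rarer entry fell (miR-15-y and miR-25-x), while miR-15-x and miR-25-y were not called (log2 fold changes of −0.09 and 0.05 with TMM scaling).

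Other called miRNAs, chosen after their values were seen, were rare or changed little. miR-183-y had 1 to 3 counts in control and 24 to 63 in IHNV libraries (edgeR, adjusted p = 0.000501). miR-204-y had 19 to 28 counts in control and 1 to 3 in IHNV libraries (edgeR, adjusted p = 0.0299). miR-221-z, which shares 22 nt with miR-221-y, went from 952 ± 51.9 to 1400.1 ± 123.6 CPM (edgeR, adjusted p = 0.0335). The predicted GATCCCTGGTCGTGCTCGGCCCCC had 35, 86 and 31 counts in the control libraries and 0 in each IHNV library. With a floor of 3 counts per library it was at least 10.5-fold lower (edgeR, adjusted p = 0.0163).

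Several explanations could account for the unequal change of -x and -y entries. Counting noise in rare entries is argued against as the whole cause, since 11 of the 19 had at least 100 counts of the rarer entry in every library. A general rise of the rarer entry is argued against, since it rose relative to the other in 7 of the 19. RNA of other animals stays open: without IHNV sample 1, which held the least of it, 16 families changed, and 14 of them lay outside the control range in the same direction in that sample, but so did 41 of the 73 unchanged families, and this rests on 1 library. A change in the use of gene copies stays open, because none of the 89 families has a letter for the copy, as does a change in processing or stability of the strands; 1 of 10 splits, the real one, gave 19 families and the highest other gave 0, and 10 splits cannot give a share under 0.05.

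The families of other lineages in IHNV samples 2 and 3 were led by miR-741-y (14262 counts in IHNV sample 2 against 84 to 360 in the others) and miR-750-y (106098 and 102718 counts in IHNV samples 2 and 3 against 3756 to 18744). A response of the rodent-lineage entries shared by the challenged fish is argued against, since IHNV samples 1 and 3 held at most 0.00858% of such counts, against 0.0130% in control sample 1. A response of the arthropod-lineage entries stays open, since a single challenged library, IHNV sample 1 (0.0752%), lay below the controls. RNA of other animals could account for both and stays open: 12 of 13 tested rodent-lineage entries were at least 5 times higher in IHNV sample 2 than in any other library, and 26 of 27 arthropod-lineage entries at least 2 times higher in both IHNV samples 2 and 3, but the families were listed after they were seen to be high there, so these counts decide nothing. The traces in the other libraries had a similar profile, with Spearman rho 0.908 over 35 rodent-lineage entries and 0.996 over 40 arthropod-lineage entries. These entries are not independent replicates. A single source for each lineage would give such a profile, though entries of the fish that vary together could give it too. Log CPM of any 2 libraries correlated at 0.925 to 0.987 (Pearson). A stable order of abundance can thus give a high rho, so these values decide nothing.

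Control sample 1 was high in miRNAs of liver, epithelium and red blood cells. A lower share of leukocytes that raises all other markers alike is argued against, since the 17 entries of the muscle and fibroblast lists had a median log2 ratio of control sample 1 to control samples 2 and 3 of −0.23. More RNA of these tissues in control sample 1 could account for part of the lower values of the lists in IHNV samples and stays open: the 24 entries of the 4 lists had a median of 1.33, but the lists were chosen because control sample 1 was high in them, so this median decides nothing. Control samples 2 and 3 held at least 18 counts of each of the 24 entries. A biological difference between the fish stays open, and a response of these cells to the virus was not separated from it.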
